A study of Homo sapiens with 16 samples.

How the data were processed

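The data are gene-level read counts of 16 RNA sequencing libraries of THP-1 macrophages, in 4 groups of 4. The groups and replicate numbers were taken from the labels, and count columns were matched to samples by the column names that the sample descriptions give. Libraries were prepared with a VAHTS Universal V6 kit, per the labels' protocols. The authors deposited whole-number counts per gene, not normalized. Per the submitters' processing notes HISAT2, HTSeq and GRCh38 were used, without roles or versions, and per the file headers the annotation is on GRCh38.p13. How reads shared between related or overlapping genes were handled, and whether strand was used in counting, is not given in the sources used here, so values of close paralogs (HLA, GBP, IFITM, CXCL1 to CXCL3, SERPINB, S100A and FCGR1 genes), overlapping genes and antisense partners are uncertain. Coordinates and symbols are those the deposited table gives. It lists 60664 genes, 20055 of them without a symbol.

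Library totals ran from 20338546 to 24149246 counts in M0, 17336637 to 23806909 in M0+iMSC, 21002872 to 24368753 in M0+LPS/IFNg and 18200706 to 23227097 in M0+LPS/IFNg+iMSC. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of libraries agreed within sampling noise, so all 16 were counted. Intervals and floors cover counting error only, and a gene with 0 counts in a group was bounded at a floor of 3 counts over the group.

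Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes kept by filterByExpr (15301, holding at least 99.9% of the counts of every library) were scaled with TMM factors, which averaged 0.984, 1.08, 0.822 and 1.14 in the groups in the order above. All 4 groups entered 1 quasi-likelihood fit with robust estimation and 12 residual degrees of freedom, without a block. The 5 contrasts were the stimulation effect, the co-culture effect without and under stimulation, the stimulation effect in co-culture, and the interaction. P-values were adjusted by the Benjamini-Hochberg method in each contrast with a threshold of 0.05. CPM values are after TMM scaling, and errors of CPM are SDs of 4 libraries. The SE of a log2 fold change was derived from the test, as its absolute value over the square root of the F statistic. It is approximate and unreliable where a group has almost no counts.

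The design, the tests, the alternatives and 30 gene lists of 544 distinct genes were fixed before the data were examined. Lists share members, so their results are not independent. Among the M1 markers, TNF, IL1B and IL6 are also in the cytokine list. CXCL9, CXCL10 and IDO1 are also in the IFN-gamma response list. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over all lists and contrasts, and with an estimated correlation as an alternative. With the estimated correlation 1 call held, the M1 polarization markers in the stimulation effect. The estimate for that list was 0.00536, below the preset, yet its camera adjusted p rose from 1.13e-07 to 0.00844. Calls lost in this alternative are therefore not by themselves evidence of correlated genes. List tests with other scaling, a block or fewer libraries kept the preset correlation. Named genes were the 8 largest rises and 8 largest falls per contrast (5 and 5 for the interaction, none for stimulation in co-culture) with an average log2 CPM of at least 3 and, outside the interaction, without overlap between groups, a fixed panel of 28 markers of which 25 were tested, and up to 4 members with the smallest p of each list described.

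Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, other filters, a minimum fold change, only the groups compared, thinned counts, a replicate block, and leaving out each library in turn. Library totals without factors, leaving out pairs of M0+iMSC libraries (replicates 1 and 2 differ from 3 and 4), and list tests and overlaps without M0+LPS/IFNg replicate 4 were chosen after seeing the data. The fit was tested on simulated data. For the co-culture effect under stimulation (14024 genes) it called 58.2%, 90% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale, with 14 false calls. For the interaction (14024 genes) it called 34.2%, 71.2% and 94.9%, with 7 false calls. All simulated groups shared the M0 means and few genes were changed, so scaling was not tested where most genes differ, as in these data. Camera called 0 of 50 random lists in simulated data. Genes were simulated independently of each other, so this does not test the preset correlation. Pathway terms were not tested because the deposited table pairs none with genes. Figures were drawn with matplotlib 3.10.9 in python 3.11.15. Results of some genes are not reported here.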

Results

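RNA was measured by sequencing in macrophages derived from THP-1, a human monocytic leukaemia cell line, in 16 libraries. All cells were first made into unpolarized macrophages (M0) with 100 ng/mL of the phorbol ester PMA for 48 hours. A 2 by 2 design then applied lipopolysaccharide (LPS) of the oral bacterium Porphyromonas gingivalis at 100 ng/mL together with interferon-gamma (IFN-gamma) at 20 ng/mL, or neither, and co-culture with mesenchymal stem cells derived from induced pluripotent stem cells (iMSCs), or none, for 48 hours. Per the labels the iMSCs sat in the upper chamber of Transwell inserts, which let soluble factors pass. The deposited count columns of both co-culture groups are named M0-CM and M1-CM, which the labels do not explain, so what is called co-culture here rests on the labels. The 4 groups, M0, M0+iMSC, M0+LPS/IFNg and M0+LPS/IFNg+iMSC, had 4 libraries each. Library totals ran from 17336637 to 24368753 counts, and 15301 genes held enough counts to be tested.

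The groups stood far apart. The first 3 principal components of log2 CPM (counts scaled to library size) took 48.9%, 32.3% and 10.4% of the variance and separated all 4 groups. Replicates of M0 lay close together, and in the other groups some libraries stood apart. M0+LPS/IFNg replicate 4 did so most: it differed at least 2-fold from the mean of the other 3 libraries of its group in 586 of 8816 well-expressed genes, where each of the other 15 libraries did so in 2 to 51. Beyond counting error, pairs that include replicate 4 differed with a coefficient of variation of 24.4% to 24.6%, and the other pairs of that group with 2.78% to 4.03%. Values without it are given beside many, but not all, of the results it moves. M0+iMSC split into replicates 1 and 2 (5.19%) and replicates 3 and 4 (3.62%), with 7.87% to 11.1% between a library of one pair and a library of the other. In M0+LPS/IFNg+iMSC, pairs with replicate 4 differed by 8.07% to 8.64% and the others by 2.96% to 5.46%. The neutrophil attractant CXCL8 alone took 9.08% ± 0.93 (SD, n = 4) of all counts in M0+LPS/IFNg, 4.13% ± 0.137 in M0, 1.80% ± 0.195 in M0+iMSC and 1.64% ± 0.104 in M0+LPS/IFNg+iMSC. Changes are therefore stated after TMM scaling. Scaling by library totals alone moved the median of all genes by -0.26 (log2) in the comparison of stimulated with unstimulated macrophages, by 0.14 and 0.47 in the co-culture comparisons without and under stimulation, by 0.07 for stimulation within co-culture and by 0.33 in the interaction.

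**Figure D1:**
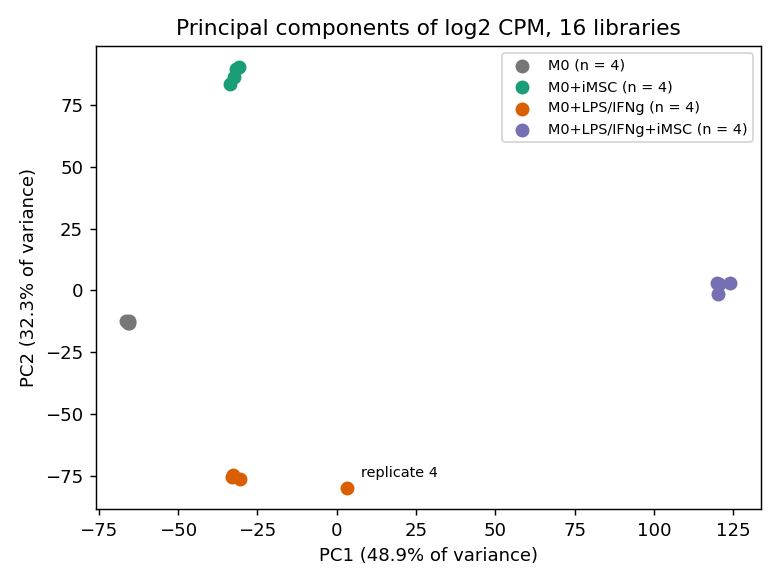
First 2 principal components of log2 CPM for the 16 libraries, coloured by group (n = 4 each), with the share of variance on each axis. The groups occupy separate places, and M0+LPS/IFNg replicate 4 sits at 3.23 on the first component where the other libraries of its group sit between -33.1 and -30.6.

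The first comparison asks what LPS with IFN-gamma did to macrophages without iMSCs. Genes of the IFN-gamma response rose: 22 of 24 tested members rose and 1 fell, with a median log2 fold change of 4.51. CXCL9, a T cell attractant (ENSG00000138755, chromosome 4, 76001275 to 76007509 on GRCh38.p13), had 0 counts in the 4 M0 libraries and 1192 ± 476 CPM (SD, n = 4) under stimulation, at least 34100-fold higher against a floor of 3 counts over the group. CXCL10 rose from 0.131 ± 0.0632 to 261 ± 45.7 CPM, IDO1, which breaks down tryptophan, from 0.0895 ± 0.0801 to 424 ± 155, and the guanylate-binding protein gene GBP5 from 0.106 ± 0.0432 to 658 ± 68.5. The transcription factor gene IRF1 rose by 3.07 ± 0.08 (log2 ± SE, edgeR adjusted p = 2.82e-15). GBP2, GBP3 and GBP4 rose by 7.85 ± 0.13, 5.18 ± 0.13 and 8.93 ± 0.18. All 25 tested type I interferon-stimulated genes rose as well, with a median of 3.70 (2.92 without replicate 4), among them IFI35 (3.54 ± 0.26) and EPSTI1 (4.08 ± 0.42). The size of several of these rises leaned on replicate 4: ISG15 rose by 3.98 with it and by 2.00 without it, OAS2 by 5.44 and 4.37, and EPSTI1 by 3.40 without it. The IDO1 rise of 12.04 leaned on M0 replicate 3, without which M0 held 3 counts, a ratio of 8670 (95% counting interval 2970 to 42100).

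Inflammatory genes rose too. Of 22 cytokine and chemokine genes 21 rose and 0 fell (median 2.71). TNF went from 93.5 ± 6.99 to 1308 ± 245 CPM, IL6 from 26.8 ± 2.40 to 532 ± 260, and CXCL8 and IL1B, already abundant in M0, rose by 1.39 ± 0.09 and 0.83 ± 0.11. EBI3, CSF3, IL32 and CXCL2 rose by 3.14 ± 0.09, 3.65 ± 0.14, 3.92 ± 0.20 and 1.99 ± 0.12. In the list of NF-kB feedback and signalling genes 16 of 18 rose (median 0.75), with SOD2 at 1.77 ± 0.09 and TNFAIP2 at 2.12 ± 0.11. PTGS2, the inducible prostaglandin synthase, rose by 1.72 ± 0.40 (adjusted p = 0.00251). CD274, which encodes the checkpoint ligand PD-L1, rose by 4.45 ± 0.12, from 13.3 ± 0.583 to 291 ± 28.2 CPM.

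Of 17 M1 polarization markers 15 rose and 0 fell (median 1.77), including IRF5 (1.78 ± 0.10), SLAMF7 (2.34 ± 0.14) and the co-stimulatory receptor gene CD40 (1.36 ± 0.10). CD80 rose by 4.18 ± 0.69 to 4.00 ± 4.02 CPM, and by 3.19 without replicate 4. CD86 stood at 0.381 ± 0.235 and 0.793 ± 0.744 CPM and did not pass (0.98, adjusted p = 0.184, and 0.12 without replicate 4). Antigen presentation genes rose throughout: all 11 MHC class II genes (median 4.89, or 3.83 without replicate 4) and all 17 of MHC class I processing (median 1.52). CIITA, the class II transactivator, rose by 4.04 ± 0.31, CTSS by 2.35 ± 0.09, and TAP2 and PSMB9 by 1.52 ± 0.05 and 3.32 ± 0.14. HLA-DRA rose by 11.40 ± 1.32, but its M0+LPS/IFNg mean of 144 ± 187 CPM rests on replicate 4 at 424, against 48.9 to 51.5 in the others, and without it the rise is 9.88. In the complement list 9 of 13 rose, led by C1S (8.45 ± 0.26) and C1R (4.72 ± 0.36). Genes of the HLA, GBP, IFITM and CXCL families have close relatives, and how reads shared between them were counted is not given in the sources used here, so single members are uncertain.

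Other genes fell. Among genes with an average log2 CPM of at least 3 the largest falls were in CCN4 (-5.69, ENSG00000104415, chromosome 8, 133191039 to 133231690), SORL1 (-4.07) and FN1, which encodes fibronectin (1410 ± 90.2 to 86.3 ± 23.8 CPM, -4.03 ± 0.19), followed by DYSF, TNFSF15, STAC2, PHLDA3 and TM6SF1 at -3.99, -3.66, -3.56, -3.38 and -3.35. The M2 polarization markers went both ways (7 rose and 2 fell of 17): IL10, CD209 and TGFB1 rose by 2.29 ± 0.23, 1.29 ± 0.15 and 0.68 ± 0.05 beside the fall of FN1. CD163, a scavenger receptor of M2 macrophages, stood at 1.37 with replicate 4 (adjusted p = 0.112) and at -0.39 without it (adjusted p = 0.163). Of 12 LXR target and lipid efflux genes 6 fell and 2 rose, with ABCG1, SCD and LPL at -1.91, -1.47 and -1.91. Of 14 TGF-beta response genes 7 fell and 2 rose, with PMEPA1 at -2.42. Of 26 cell cycle genes 7 fell and 1, CCNE2, rose (2.15).

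In all, 8779 of 15301 genes differed (edgeR quasi-likelihood test, adjusted p under 0.05), 4451 higher and 4328 lower, of which 2678 differed at least 2-fold. The 4 libraries of each group did not overlap in 52.2% of genes, where chance gives 2.86%. The split of directions depends on the scaling: library totals alone gave 2520 higher and 6938 lower. Camera called the lists of IFN-gamma response (adjusted p = 7.03e-16), type I interferon-stimulated genes (4.88e-08), cytokines (1.92e-10), NF-kB (4.75e-06), M1 markers (1.13e-07), MHC class II (4.09e-07), MHC class I (1.02e-11) and complement (0.00143), beside inflammasome (0.00331) and glycolysis (0.00852). With an estimated correlation the M1 marker call held at adjusted p = 0.00844. The others were lost, at adjusted p = 0.145, 0.580, 0.145, 0.109, 0.471, 0.331, 0.507, 0.489 and 0.489 with an estimated correlation, in the same order. Adjusted over the list alone, the counts of the 12 lists described above were the same except that 23 IFN-gamma response genes rose and 2 NF-kB, 7 LXR and 8 TGF-beta response genes fell. The lists of M2 markers, LXR targets, TGF-beta response and cell cycle were not called (adjusted p = 0.159, 0.0810, 0.182 and 0.134), though the LXR list was without replicate 4 (adjusted p = 0.0132) and the M2 list with library totals alone (0.0142).

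The second comparison asks what iMSCs in the insert did to unstimulated macrophages. Cell cycle genes rose: 20 of 26 rose and 0 fell, with a median log2 fold change of 2.44. The proliferation marker MKI67 went from 2.10 ± 0.258 to 59.95 ± 21.1 CPM (SD, n = 4), TOP2A, a topoisomerase of dividing cells, from 0.797 ± 0.154 to 57.4 ± 20.3, CDK1 from 0.519 ± 0.0818 to 20.7 ± 7.37 and the mitotic kinesin gene KIF2C from 0.336 ± 0.122 to 24.8 ± 8.59. BUB1B and PLK1 rose by 4.65 ± 0.31 and 3.17 ± 0.23. The other large rises were in SERPINA9 (7.25 ± 0.47, ENSG00000170054, chromosome 14, 94462717 to 94479689), the scavenger receptor gene MARCO (0.343 ± 0.0675 to 32.0 ± 3.13 CPM), the chemokine gene CCL1 (5.17 ± 0.38) and the gap junction gene GJB2 (5.15 ± 0.21). M0+iMSC replicates 1 and 2 stood above replicates 3 and 4 in several of these: MKI67 was at 72.0 and 83.3 CPM against 45.3 and 39.2, TOP2A at 67.8 and 80.8 against 40.5 and 40.3, and SERPINA9 at 86.9 and 85.3 against 34.2 and 34.2. Without replicates 1 and 2 the rises of these 3 genes were 4.33, 5.64 and 6.44, and without replicates 3 and 4 they were 5.21, 6.53 and 7.77.

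Several inflammatory genes fell. PTGS2 dropped from 2270 ± 108 to 107 ± 52.5 CPM (-4.41 ± 0.45), CXCL8 from 42040 ± 1490 to 16600 ± 1960, and IL6 changed by -2.20 ± 0.43 (log2). The cytokine list was mixed, with 11 of 22 down and 6 up: CCL3 and CSF3 changed by -2.42 and -2.96, while TNF rose by 1.15 ± 0.20 and EBI3 by 1.80 ± 0.09. CCL2 rose by 1.06 ± 0.32. Without M0+iMSC replicates 1 and 2 it stood at 0.24 (adjusted p = 0.327). IL1B changed by -0.26 at adjusted p = 0.0439, a call lost, at adjusted p = 0.0564 to 0.112, without any 1 of the M0 libraries or M0+iMSC replicates 1, 3 or 4. In the NF-kB list 13 of 18 fell and 3 rose, with TRAF1, RELB, BIRC3 and NFKBIA at -1.86, -1.26, -1.52 and -1.08. Immediate early genes fell in 11 of 16 cases and rose in 3, including KLF6 (-2.30), MYC (-1.67) and FOSB (-3.85). The cAMP and prostaglandin E2 list had 12 falls and 4 rises among 20, with DUSP1 at -2.81 and VEGFA at 1.00. The NRF2 list had 11 falls and 3 rises among 16, with SLC7A11 at -1.85 and GCLM at 0.87. Inflammasome and pyroptosis genes, in contrast, rose in 10 of 14 cases and fell in 1.

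Of 24 IFN-gamma response genes 13 rose and 1, IRF1, fell (-0.64 ± 0.07). GBP2 rose by 3.25 ± 0.12 and GBP3 by 2.66 ± 0.12. Of 25 type I interferon-stimulated genes 8 rose and 0 fell. Of 17 osteoclast differentiation genes 8 fell and 5 rose: TNFRSF11A, which encodes the receptor RANK, fell from 29.8 ± 2.48 to 2.06 ± 0.240 CPM, and CA2 and SRC stood at -1.81 and -0.72. CD209 rose by 2.15 ± 0.15 and CD163 fell from 31.3 ± 0.858 to 2.77 ± 1.14 CPM. At an average log2 CPM of at least 3 the largest falls were in NEK10 (-5.35, ENSG00000163491, chromosome 3, 27110085 to 27369460), SLC43A2 (-4.90), GUCY1A2 (-4.88), EDN1 (-4.59) and MMP10 (-4.56). Of 16 tested mesenchymal stromal cell markers 10 rose and 2 fell (median 0.89, or 1.10 with 2 members at their bound against a group with 0 counts). COL6A3 went from 13.8 ± 1.00 to 282 ± 8.09 CPM and COL1A1 from 1.67 ± 0.331 to 6.16 ± 1.98, while COL1A2 had 0 counts and COL3A1 8 counts over all 8 co-culture libraries.

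This comparison called 10681 genes, 5544 higher and 5137 lower, of which 4073 differed at least 2-fold, and the groups did not overlap in 69% of genes. With library totals alone the split was 6541 higher and 4093 lower. Camera called cell cycle (adjusted p = 4.82e-06), NF-kB (0.00136), IFN-gamma response (0.00425), inflammasome (0.0227), NRF2 (0.0241), immediate early genes (0.0262) and cAMP (0.0456), none of which held with an estimated correlation (adjusted p = 0.580, 0.206, 0.580, 0.580, 0.489, 0.542 and 0.507). Cytokines, osteoclast genes, mesenchymal markers and type I interferon-stimulated genes were not called (adjusted p = 0.134, 0.296, 0.0506 and 0.0843), though the latter 2 lists were without M0+LPS/IFNg replicate 4 (adjusted p = 0.0331 and 6.87e-04) and the cytokine list with library totals alone (0.0473). The mesenchymal list was also called with a replicate block (adjusted p = 0.0411). Adjusted over the list alone, the counts of these 11 lists were the same except that 21 cell cycle and 5 type I interferon-stimulated genes rose.

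The third comparison, named by the study's title, asks how iMSCs changed macrophages under LPS with IFN-gamma. Inflammatory genes fell. None of 22 cytokine and chemokine genes rose and 18 fell, with a median of -2.52. TNF dropped from 1308 ± 245 to 38.4 ± 11.0 CPM (SD, n = 4), against 93.5 ± 6.99 in M0, IL6 from 532 ± 260 to 19.9 ± 3.46, IL1B from 46640 ± 8250 to 7545 ± 816, CXCL8 from 110400 ± 10400 to 14400 ± 1030, and CSF3 changed by -6.73 ± 0.17 (log2). PTGS2 went from 7456 ± 3430 to 181 ± 27.4 CPM (-5.36 ± 0.47, adjusted p = 2.04e-07). CCL2 was an exception at 334 ± 67.7 and 504 ± 102 CPM (adjusted p = 0.0873). It passed in several alternatives, with adjusted p = 0.0460 without replicate 4 and 0.00471 with library totals alone. In the NF-kB list 16 of 18 fell and 2 rose, with BIRC3, CFLAR and NFKBIA at -3.70, -1.26 and -1.22 and the signalling inhibitor gene IRAK3 at 1.72. Immediate early genes fell in 11 of 16 cases and rose in 3, with EGR2 and IER3 at -3.62 and -2.61 and MYC at 1.41.

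IFN-gamma response genes fell as well, 18 of 24, with 3 up (median -1.21). CXCL9 fell from 1192 ± 476 to 3.04 ± 1.75 CPM, CXCL10 from 261 ± 45.7 to 16.1 ± 7.32, IDO1 from 424 ± 155 to 12.8 ± 5.60 and CD274 from 291 ± 28.2 to 14.0 ± 2.93. IRF1 changed by -2.14 ± 0.07 and the tRNA synthetase gene WARS1 by -2.93 ± 0.07. TBX21, which encodes the transcription factor T-bet (ENSG00000073861, chromosome 17, 47733236 to 47746122), had the largest fall at an average log2 CPM of at least 3, from 23.2 ± 8.62 CPM to 1 count over 4 libraries, a ratio of 2200 (95% counting interval 394 to 86800). Without M0+LPS/IFNg+iMSC replicate 2, which held that count, TBX21 was at least 540-fold lower against a floor of 3 counts over the group. Type I interferon-stimulated genes did not follow: 3 of 25 fell and 1 rose. This list depended on replicate 4. Without it the median moved from 0.53 (adjusted p = 0.582) to 1.43 (adjusted p = 0.00176), and ISG15 turned from -0.53 (adjusted p = 0.511) to a rise of 1.45 (adjusted p = 7.55e-09). Both list values use the preset correlation. With an estimated correlation over all libraries the list had adjusted p = 0.952. Of 11 MHC class II genes 6 fell and none rose, with CIITA and HLA-DRA at -1.67 and -3.56 (-2.05 without replicate 4).

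**Figure D2:**
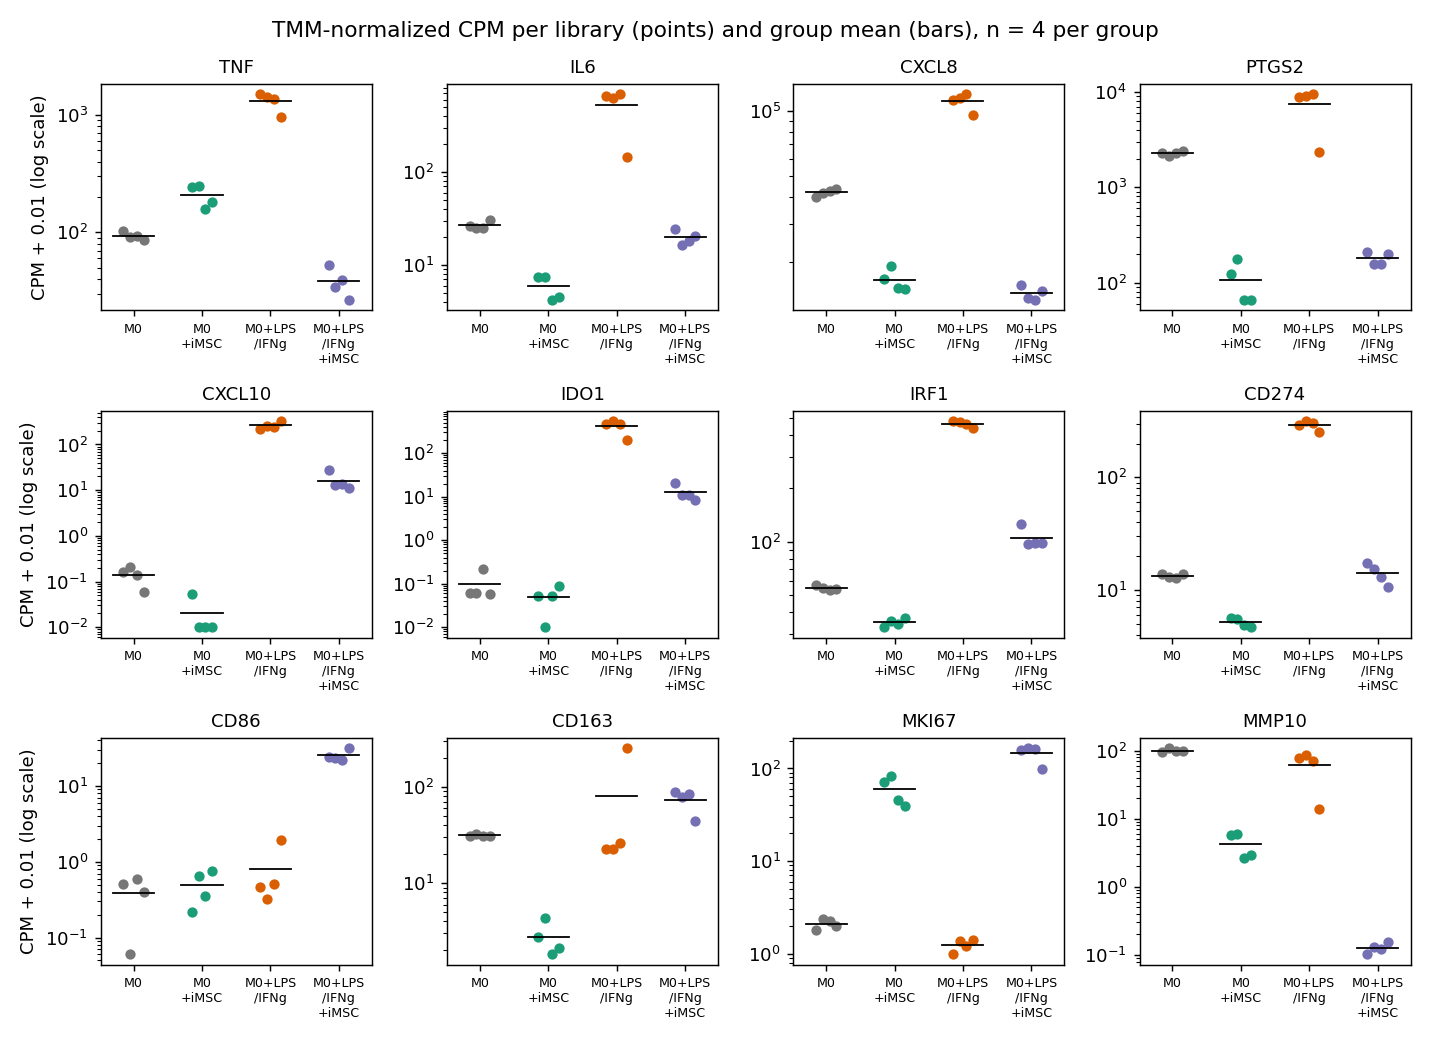
CPM after TMM scaling (log axis, 0.01 added) of 12 genes in each of the 16 libraries, by group, with a bar at the mean of 4 libraries. TNF, IL6, CXCL8, PTGS2, CXCL10, IDO1, IRF1 and CD274 are highest under stimulation without iMSCs, MKI67 is highest in both co-culture groups, and M0+LPS/IFNg replicate 4 lies apart in IL6, PTGS2 and CD163.

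Among M1 polarization markers 13 of 17 fell and 3 rose (median -1.23). CCR7 changed by -2.47 ± 0.21 and CD40 by -0.67 ± 0.10, though with library totals alone CD40 stood at -0.19 (adjusted p = 0.0798). CD86, counted as an M1 marker and encoding a T cell co-stimulator, rose from 0.793 ± 0.744 to 25.2 ± 4.17 CPM, all 4 libraries above all 4 (5.01, and 5.87 without replicate 4). CD80 stood at 0.55 (adjusted p = 0.266) and at 1.54 without replicate 4 (adjusted p = 3.97e-07). M2 polarization markers went both ways, 10 of 17 up and 4 down: VSIG4 rose by 5.29 ± 0.31, FN1 by 3.45 ± 0.19 and CD209 by 0.87 ± 0.14, while TGFB1, TGM2 and IL10 changed by -1.24, -1.59 and -1.82. CD163 was at -0.13 (adjusted p = 0.867) with replicate 4 and rose by 1.62 without it (adjusted p = 2.21e-05). In the monocyte and macrophage identity list 10 of 17 rose and 4 fell, with CD33 and MARCO up by 1.99 ± 0.10 and 4.80 ± 0.37 and CEBPB and ITGAX at -1.14 and -0.99. LXR targets rose in 8 of 12 cases and fell in 1, including the cholesterol exporter gene ABCG1 (2.50 ± 0.11), PLTP (1.77 ± 0.10) and SREBF1 (1.04 ± 0.07). Without replicate 4 VSIG4 and MARCO rose by 6.00 and 5.78. The panel members IL12B, MRC1 and ARG1 had at most 7, 5 and 1 counts in any library and were not tested.

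Of 21 matrix proteases and inhibitors 15 fell and 3 rose (median -2.28): MMP3 went from 573 ± 282 to 0.918 ± 0.0606 CPM, MMP10 from 62.5 ± 32.9 to 0.118 ± 0.0224, SERPINB2 from 1537 ± 857 to 7.70 ± 1.40, and MMP7, MMP19 and the inhibitor gene TIMP1 changed by -3.18, -3.29 and -1.69. MMP9 did not pass (-0.35, adjusted p = 0.123). Of 17 osteoclast differentiation genes 11 fell and 3 rose. OCSTAMP, a cell fusion gene, fell from 48.5 ± 24.1 to 0.168 ± 0.141 CPM (ENSG00000149635, chromosome 20, 46540946 to 46550654), and its relative DCSTAMP, TNFRSF11A, CA2 and SRC changed by -2.59, -2.35, -3.17 and -1.78. CEMIP, which takes part in hyaluronan breakdown, and MDGA1 also fell from 71.3 ± 8.75 to 0.250 ± 0.240 and from 40.6 ± 17.8 to 0.193 ± 0.0495 CPM. Leaving out M0+LPS/IFNg+iMSC replicate 1 moved OCSTAMP from -8.19 to -8.87 and CEMIP from -8.14 to -8.94.

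Cell cycle genes rose in 25 of 26 cases with none falling (median 3.17). MYBL2, a transcription factor gene of dividing cells (ENSG00000101057, chromosome 20, 43667019 to 43716495), went from 0.0934 ± 0.0812 to 53.7 ± 12.4 CPM, MKI67 from 1.23 ± 0.188 to 145 ± 31.8, TYMS from 0.464 ± 0.154 to 55.7 ± 12.6, and KIF2C, BUB1B, CCNA2 and TOP2A rose by 7.44, 7.22, 6.89 and 6.79. All 5 tested genes chosen as markers of undifferentiated THP-1 cells also rose here, ELANE by 1.95, PRTN3 by 1.89, AZU1 by 1.88, CTSG by 2.42 and MYB by 2.36, so less differentiated cells may contribute. Their levels were low: in CPM by library totals they went from 0.549 to 2.92, 0.502 to 2.56, 3.60 to 18.3, 0.448 to 3.35 and 0.468 to 3.34, in the same order. MPO, not tested, stood at 0.0443 and 0.0598. FPR1, a receptor for bacterial formyl peptides, rose from 0.340 ± 0.0816 to 66.8 ± 17.4 CPM. Nuclear genes of oxidative phosphorylation rose in 18 of 25 cases and fell in 2, by small amounts (median 0.33), ATP5MC3 by 0.78 ± 0.05. Mitochondrially encoded genes fell in 11 of 13 cases (median -0.48, MT-ND2 at -0.83). With library totals alone the call of the latter list ended (adjusted p = 0.109). Mesenchymal stromal cell markers went both ways (6 up and 7 down of 16), with DCN at 0.0662 ± 0.0779 and 18.8 ± 2.02 CPM, PRRX1 at -4.54 and COL1A1 at 0.33 (adjusted p = 0.153), or 0.80 with library totals alone (adjusted p = 0.00210). The DCN rise of 8.01 leaned on M0+LPS/IFNg replicate 3, without which that group held 2 counts, a ratio of 513 (95% counting interval 142 to 4240).

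Under stimulation co-culture changed 11431 genes, 5876 higher and 5555 lower, of which 5203 differed at least 2-fold, and 65.9% of genes did not overlap between the groups. With library totals alone the split was 9020 higher and 3066 lower. Camera called cell cycle (adjusted p = 3.87e-09), cytokines (1.38e-05), NF-kB (6.13e-04), matrix proteases (8.95e-04), IFN-gamma response (0.00413), mitochondrially encoded genes (0.0117), osteoclast genes (0.0128), M1 markers (0.0175), immediate early genes (0.0241) and oxidative phosphorylation (0.0241). None held with an estimated correlation (adjusted p = 0.507, 0.331, 0.201, 0.176, 0.580, 0.70, 0.343, 0.206, 0.532 and 0.70). M2 markers, macrophage identity and LXR targets were not called (adjusted p = 0.264, 0.166 and 0.0699) and each was without replicate 4 (0.0493, 0.0282 and 0.0207), all with the preset correlation. With an estimated correlation over all libraries these lists had adjusted p = 0.764, 0.843 and 0.580. MHC class II and mesenchymal markers were not called (adjusted p = 0.166 and 0.795) and the former was with library totals alone (adjusted p = 0.0352). Adjusted over the list alone, the counts of these 16 lists were the same except that 13 mitochondrially encoded genes fell, and 0 type I interferon-stimulated genes rose and 1 fell.

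**Figure D3:**
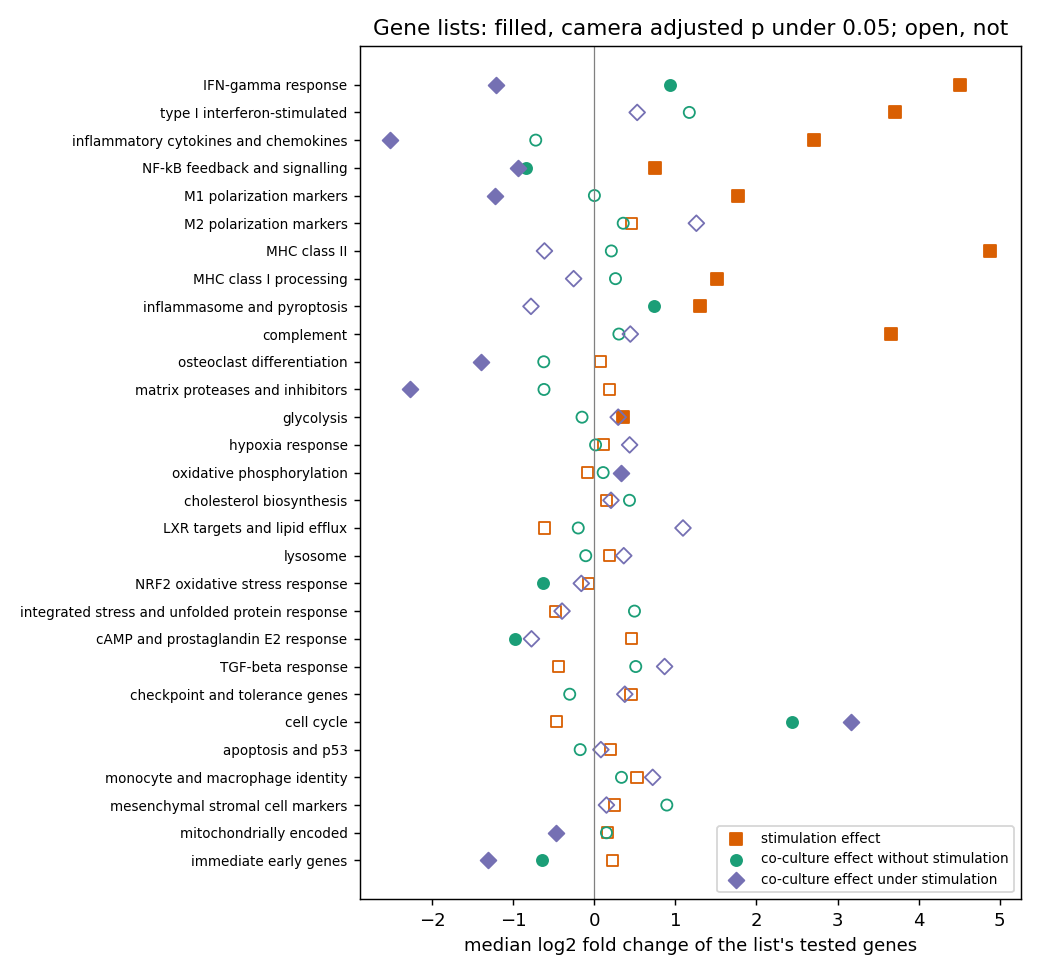
Median log2 fold change of the tested genes of 29 lists in 3 comparisons, filled where camera with its preset correlation gave an adjusted p under 0.05 and open otherwise. Cytokines, IFN-gamma response and M1 markers, lists that share members, lie right of 0 under stimulation and left of 0 for co-culture under stimulation. Cell cycle genes lie at 2.44 and 3.17 for the co-culture effects.

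The fourth comparison asks what LPS with IFN-gamma did to macrophages kept with iMSCs. Against M0+iMSC, 20 of 24 IFN-gamma response genes rose and 2 fell (median 1.97), with GBP1 up by 6.66 ± 0.19. CXCL9 had 0 counts in M0+iMSC and 3.04 ± 1.75 CPM with stimulation, at least 88.6-fold higher. Type I interferon-stimulated genes rose in 23 of 25 cases, MHC class II genes in 10 of 11 and complement genes in 13 of 13, C1S by 6.28 ± 0.24. CCL2, CD86 and CD163 rose by 3.24 ± 0.33, 5.69 ± 0.40 and 4.76 ± 0.86. The cytokine list was mixed, 10 up and 7 down of 22 (adjusted p = 0.451): IL6 rose by 1.77 ± 0.43, while TNF and IL1B were lower with stimulation (-2.44 ± 0.21 and -1.54 ± 0.11). MHC class I, glycolysis, cell cycle, NF-kB and lysosome genes rose in 16 of 17, 15 of 20, 22 of 26, 14 of 18 and 14 of 20 cases and fell in 1, 3, 0, 4 and 2. Matrix proteases fell in 13 of 21 cases and rose in 5, and mitochondrially encoded genes fell in 10 of 13 and rose in 0. Integrated stress and unfolded protein response genes fell in 16 of 20 cases, with DDIT3 at -3.17 ± 0.12. In total 11382 genes differed, 6010 higher and 5372 lower (6534 and 4876 with library totals alone), 4945 of them at least 2-fold. Camera called 12 lists: IFN-gamma, type I, MHC class II, complement and stress (adjusted p = 3.41e-05, 3e-04, 0.00379, 3e-04 and 0.00379), and MHC class I, glycolysis, cell cycle, NF-kB, lysosome, matrix and mitochondrial genes (adjusted p = 7.95e-05, 0.00124, 0.00261, 0.0148, 0.0422, 0.0203 and 0.0266). It lost each with an estimated correlation (adjusted p = 0.476, 0.754, 0.662, 0.476 and 0.563, and 0.580, 0.343, 0.754, 0.343, 0.842, 0.331 and 0.754). Adjusted over the list alone, these counts were the same.

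The interaction tests whether iMSCs changed stimulated macrophages otherwise than unstimulated ones. TNF rose with iMSCs in M0 (1.15 ± 0.20) and fell under stimulation (-5.09 ± 0.23), an interaction of -6.24 ± 0.30 (adjusted p = 4.33e-10). At an average log2 CPM of at least 3 the most negative interactions were in TBX21 (56.1 ± 7.83 CPM in M0+iMSC and 0.0102 ± 0.0204 in M0+LPS/IFNg+iMSC), OCSTAMP (391 ± 48.6 and 0.168 ± 0.141), MDGA1, ARNT2 and XIRP1, at -12.67, -9.76, -8.83, -8.80 and -8.78. The most positive were in GAPT, the adhesion receptor genes ADGRE1 and ADGRE3, FPR1 and MYBL2, at 6.28, 6.01, 5.24, 5.83 and 5.77, and CD86 stood at 4.71. Without M0+LPS/IFNg replicate 4 GAPT and CD86 moved to 7.60 and 5.58, and without M0+LPS/IFNg+iMSC replicate 1 OCSTAMP to -10.44. The size for TBX21 rests on 1 count in M0+LPS/IFNg+iMSC, in replicate 2, and without that library only a lower bound on it could be given. Interactions passed as negative in 15 of 24 IFN-gamma response genes (GBP2 -4.87), 14 of 22 cytokine genes (EBI3 -2.58), 15 of 21 matrix genes (TIMP1 -3.40) and 13 of 17 MHC class I genes (HLA-E -1.72), and as positive in 18 of 26 cell cycle genes (MCM3 2.75) and 8 of 12 LXR targets (SREBF1 1.41). Camera called all of these 6 lists (adjusted p = 2.48e-07, 3e-04, 0.00370, 0.00536, 2.54e-04 and 0.0177), none with an estimated correlation (adjusted p = 0.331, 0.406, 0.206, 0.709, 0.70 and 0.507). Adjusted over the list alone, these counts were the same. It also called 5 lists as negative, stress response, mitochondrially encoded, inflammasome, MHC class II and M1 markers (adjusted p = 0.00825, 0.00961, 0.0128, 0.0261 and 0.0345), again none with an estimated correlation (adjusted p = 0.580, 0.70, 0.563, 0.754 and 0.331). The call of M1 markers ended without M0+LPS/IFNg replicate 4 (adjusted p = 0.0742). The NF-kB and immediate early lists were not called (camera adjusted p = 0.824 and 0.750). NF-kB genes had co-culture medians of -0.85 without and -0.94 under stimulation. The PTGS2 interaction did not pass (-0.96, edgeR adjusted p = 0.152), though it did without replicate 4 (-1.25, adjusted p = 0.0129). Nor did CXCL10, IDO1 and HLA-DRA (adjusted p = 0.909, 0.269 and 0.510), which were near the floor without stimulation. In total 9506 genes had an interaction, 4752 positive and 4754 negative, or 7029 and 3108 with library totals alone.

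Across genes the log2 fold changes of both co-culture effects, which share no library, correlated with a Pearson r of 0.41 and a Spearman rho of 0.42. Genes are not independent replicates, so this describes the profiles only. Of the called genes 3192 rose in both states and 2981 fell in both, where independent lists of these sizes would share 2129 and 1865. Another 1163 rose without and fell under stimulation, and 942 fell without and rose under it. All 2105 of these also passed the interaction test, which adds little, since the interaction is the difference of both effects.

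The last comparison asks how many genes co-culture moved against the direction of stimulation. Opposite directions do not mean a return to the level in M0: PTGS2 stood at 2270 CPM in M0, 7456 under stimulation and 181 with iMSCs added, and CXCL8 at 42040, 110400 and 14400. Of the 4451 genes that rose with stimulation, 2262 fell when iMSCs were added, where independent lists would share 1616. Of the 4328 that fell, 2033 rose, against 1662. In the same direction as stimulation, 1233 rose in both and 1294 fell in both. These overlaps were not counted with library totals alone, which change the directions in both comparisons. That scaling gave 2520 higher and 6938 lower for stimulation, and 9020 and 3066 for co-culture under it. Both comparisons use the M0+LPS/IFNg libraries with opposite signs, so some opposite movement arises by chance. Simulated unchanged groups sharing these libraries gave 0 to 1 opposite genes in 20 simulations. With no gene truly changed almost none could pass, so that count cannot show how many opposite genes the sharing produced. The simulations gave a median Pearson r of -0.53 and a median covariance of -0.02. Observed were an r of -0.15 and a covariance of -0.20, a difference in covariance of -0.18. With the 4 libraries split 2 and 2 so that the comparisons shared none, 3392 to 3827 genes moved in opposite directions over the 6 assignments, 1.19 to 1.44 times the number expected from independent lists of these sizes, and r lay between -0.21 and -0.04. Of 232 genes raised at least 8-fold by stimulation, a set chosen after seeing the data, 109 fell with iMSCs, 46 rose further and 77 did not pass. Without replicate 4 these were 123, 76 and 25 of 224.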

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

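The tests of a swapped or mixed library, of scaling, of shared libraries, of a weaker stimulus and of undifferentiated cells under stimulation were chosen only after the results were seen, as was the use of COL1A2 and COL3A1 to weigh iMSC RNA.

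Chance was tested by regrouping the libraries. Of 35 splits of the 8 libraries into 4 and 4, 1, the real one, called as many genes in each of 4 comparisons: 8779 for stimulation against at most 205 in another split, 10681 for co-culture without stimulation against 0, 11431 for co-culture under stimulation against 1140, and 11382 for stimulation in co-culture against 0. The split with 1140 exchanges replicate 4 of M0+LPS/IFNg with a library of the co-culture group. For the interaction 1 of 100 draws, the real one, reached 9506 genes. The highest other draw called 8341 and had all stimulated and 2 unstimulated labels exchanged, so it carries the co-culture effect itself. The real grouping stood out from every other one, though 1 of 35 is the smallest share these splits allow. Splits that mix groups this far apart raise the spread and so call few genes. They cannot tell the treatments from other differences between the cultures of the groups. For the interaction, shuffled labels also break up the co-culture effects, so the draws do not decide whether an interaction exists.

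A library far from the other 3 of its group was found for 16 of 96 pairs of panel gene and group, where chance gives about 1 in 20. In 11 of these the library was M0+LPS/IFNg replicate 4. Its CPM was higher than the range of the others for CCL2 (435 against 292 to 308), CD80 (10 against 1.76 to 2.23), CD86 (1.9 against 0.311 to 0.502), CD40 (69.2 against 46.6 to 49.2), HLA-DRA (424 against 48.9 to 51.5), ISG15 (184 against 13.4 to 15.6), CD163 (252 against 22.5 to 26.1) and MMP9 (2400 against 1140 to 1210). It was lower for IL1B (34300 against 49900 to 51700), IL6 (144 against 631 to 692) and PTGS2 (2330 against 8930 to 9510). The others included IRF1 and CXCL10 in M0+LPS/IFNg+iMSC replicate 1 (125 and 27 CPM) and COL1A1 in M0+LPS/IFNg+iMSC replicate 4 (13.1). The rest were IDO1 in M0 replicate 3 (0.21 against 0.0484 to 0.0501) and CXCL10 in M0+iMSC replicate 1 (0.0421 against 0). Both of the latter rest on very few counts. Among 504 other genes 1 library stood apart for 39 in M0, 17 in M0+iMSC, 210 in M0+LPS/IFNg (203 of them replicate 4) and 48 in M0+LPS/IFNg+iMSC.

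In M0+LPS/IFNg replicate 4, type I interferon-stimulated genes, MHC class II genes and M2 markers lay above the mean of replicates 1 to 3 by a median of 2.77, 2.28 and 1.81 (log2), and cytokines at -0.46. A swap with a co-culture library is argued against, since 0 of the M0+LPS/IFNg+iMSC libraries lay closer to replicates 1 to 3 than to their own group. RNA of the other groups mixed in is argued against by the 25.1% of its 2-fold differing genes (147 of 586) that lay outside the range of all 15 other libraries. A culture that differed, or a sample from outside these groups, stays open. No biological explanation was tested, since the labels give this library no condition of its own.

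Cell cycle genes were higher in both co-culture groups. Scaling is argued against: a factor between libraries moves all genes alike, but at most 2.91% of the other tested genes rose as far as the median of the list in either state (445 of 15275 without stimulation and 358 under it). RNA of iMSCs in the lysates is argued against by COL1A2 and COL3A1, abundant in mesenchymal cells, which reached at most 0.329 CPM in the co-culture libraries, although the bounds set beforehand were not met (COL1A1 passed 10 CPM in 1 co-culture library, and the stromal marker median was 0.89 without stimulation). Other stromal markers did rise, COL6A3 by 4.35 without and DCN by 8.01 under stimulation. Of 16 tested, 10 rose and 2 fell without stimulation, and 6 rose and 7 fell under it. Cells that had not differentiated would bring genes of undifferentiated THP-1, here granule genes and the transcription factor gene MYB. Without stimulation 1 of 5 tested genes, CTSG, rose and AZU1 fell. This argues against such cells there only weakly, since levels were low. From M0 to M0+iMSC ELANE went from 0.377 to 0.516 CPM by library totals and PRTN3 from 1.29 to 0.656. MPO, with too few counts to be tested, went from 0.0675 to 0.395. Under stimulation 5 of the tested genes rose. Less differentiated cells may therefore account for part of the pattern under stimulation, and an effect of co-culture itself remains a hypothesis. The levels of these genes were low there, from 0.0598 CPM for MPO to 18.3 for AZU1 in M0+LPS/IFNg+iMSC by library totals.

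Many genes moved against the direction of stimulation when iMSCs were added under it. Noise of single shared libraries, as the only cause, is argued against. With the libraries split, genes moving in opposite directions were still at least 1.19 times as many as independent lists would share. In that assignment they were 3413 against 2862, with 2584 in the same direction. In the 3 assignments that kept replicate 4 out of the stimulation effect the ratio was 1.44. A deviation common to all M0+LPS/IFNg libraries would remain in both comparisons with opposite signs. The split cannot decide whether such a deviation contributed. A weaker stimulus alike for every gene, as the only effect of co-culture, is argued against, since 19.8% of the genes raised at least 8-fold rose further in co-culture. Among all tested genes 5876 of 15301 rose there. A weaker stimulus together with a general effect of co-culture could give such rises and stays open. Unequal weakening, and effects of co-culture unrelated to the stimulus, stay open and were not tested.

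The effects of co-culture differed between the stimulation states in 9506 genes by the interaction test. Of these, 2105 were called in opposite directions in the 2 states. The interaction of -6.24 in TNF (log2) is an example.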

How the results depend on the processing

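Library totals without factors and leaving out M0+iMSC pairs were chosen only after results were seen. Of 338 pairs of gene and comparison, 300 kept direction and side of the threshold in every alternative but the 2-fold minimum, which ended 36 calls. DESeq2 gave 319 of these values. Counts of called genes stayed within 8144 to 9222, 10238 to 11612, 11110 to 12095, 11133 to 12214 and 9165 to 10338 when 1 library was left out, in the order stimulation, co-culture without and under stimulation, stimulation in co-culture, and interaction. With a 2-fold minimum they were 2678, 4073, 5203, 4945 and 4589, fewer by construction. Of 150 list tests 50 were called, 1 with an estimated correlation and 118 with fry, which asks another question. Genes called in opposite directions by stimulation and by co-culture under it numbered 4295, or 906 at 2-fold in both.

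Leaving out 1 library turned ISG15 under co-culture with stimulation (-0.86 to 1.45, highest without M0+LPS/IFNg replicate 4), CD163 there (-0.45 to 1.62, likewise) and the ISG15 interaction (-1.51 to 0.80, likewise). CD209, stimulation effect in co-culture, went from 0.01 to -0.26 without M0+iMSC replicates 1 and 2. The NFKBIA interaction went from -0.14 to 0.19 with library totals alone. The cause was not tested. Depth limits genes with few counts, such as IL12B and ARG1.

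Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated between -0.106 and 0.172, over 0.1 in 1 of 24 pairs, and 2 of 16 libraries correlated best with their own number. With a replicate block 8636, 10583, 11368, 11344 and 9395 genes were called, and list tests called 53.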

Other observations

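The single genes here were chosen only after their values were seen, as was the lysosome test without M0+LPS/IFNg replicate 4, and the other list tests were planned. S100A8 and S100A9, which encode the subunits of calprotectin, rose with co-culture under stimulation from 134 ± 23.0 to 2314 ± 540 and from 386 ± 99.8 to 3290 ± 697 CPM (SD, n = 4), with edgeR log2 fold changes of 4.11 ± 0.23 and 3.09 ± 0.23 (± SE). Without stimulation neither passed (adjusted p = 0.262 and 0.308), and their interactions were 3.71 ± 0.38 and 3.37 ± 0.32. The proteoglycan gene VCAN rose by 5.86 ± 0.34 under stimulation. IL18, which encodes a cytokine of the interleukin 1 family, rose in both states, by 2.38 ± 0.12 without and 3.32 ± 0.13 under stimulation. S100A genes have close relatives, so single members are uncertain.

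Glycolysis genes rose with stimulation in 12 of 20 cases and fell in 1 (camera adjusted p = 0.00852, and adjusted p = 0.489 with an estimated correlation; adjusted over the list alone 12 rose and 2 fell). Lysosome genes were 7 up and 4 down of 20 for co-culture under stimulation (adjusted p = 0.430, and adjusted p = 0.901 with an estimated correlation). With the preset correlation the list was called without M0+LPS/IFNg replicate 4 (adjusted p = 0.0117). Inflammasome and pyroptosis genes rose in 10 of 14 cases with stimulation and fell in 3 (adjusted p = 0.00331, and adjusted p = 0.489 with an estimated correlation). Adjusted over the list alone, the counts of the lysosome, inflammasome and cholesterol lists were the same. Cholesterol biosynthesis genes were mixed for co-culture under stimulation, 10 up and 7 down of 21 (adjusted p = 0.928).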
